A study of Mus musculus with 8 samples.

How the data were processed

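Ribosome footprints and total RNA were measured in cultures of neurons at day 8 in vitro, with 2 libraries in each of 4 groups. Per the labels' protocols, translation was stopped with cycloheximide at 100 µg/ml for 5 minutes and footprints were prepared with the ARTseq kit. Cycloheximide given before lysis can shift where footprints lie along a transcript, and the values here are sums over whole genes. Per the submitters' processing notes, FastQC, Trimmomatic, Bowtie and kallisto were used, without versions. The genome build, the transcript set and the settings are not given in the sources used here, nor is whether counting used strand. The deposited table holds estimated counts per Ensembl transcript, whole numbers throughout, so that no rounding was needed here. kallisto divides reads among isoforms and among similar genes, so that counts of genes with near-identical copies and overlapping genes are uncertain.

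The table held 60528 transcripts, of which 60444 (99.86%) matched transcript identifiers of GENCODE M21 (GRCm38). The other 84 held 0.076% to 0.151% of the counts of a library and were left out. Counts were summed over the isoforms of a gene, giving 18301 genes, none of them mitochondrial. Isoforms annotated as retained introns (13063) and processed transcripts (8516) were included in the sums, and took 11.04% to 11.54% of the footprint counts and 7.57% to 7.86% of the RNA counts. The depth was 10490535 to 19753419 counts in footprints and 14762047 to 44786643 in RNA. The median SE of a log2 fold change was 0.13 in footprints, 0.12 in RNA and 0.18 in translational efficiency.

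All 8 libraries were fitted in 1 edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with a mean for each of the 4 groups, TMM scaling and robust dispersion estimates, which left 4 residual degrees of freedom. Genes were kept where filterByExpr, with its minimum count of 10, passed in both the footprint and the RNA libraries, which left 12898 genes tested and 5403 not tested. The contrasts were DKO minus WT in footprints, in RNA and, as an interaction, in footprints relative to RNA (translational efficiency). Benjamini-Hochberg adjusted p-values under 0.05 were called. Of 31 gene lists fixed in advance, the 26 with at least 5 tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. The replication-dependent histone, mitochondrially encoded, pluripotent, microglia and blood, and Y-linked lists had fewer than 5 and were not tested. The lists, the model and most alternatives were fixed before the data were examined.

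Named genes followed a rule fixed at the same time. For each contrast it takes up to 10 genes per direction with the largest changes among called genes whose 2 DKO values lie beyond both WT values and whose mean is at least 1 CPM, or the 5 with the smallest p per direction where fewer than 5 pass. It adds Eif4g1, Eif4g3 and 5 partners, and for each list up to 4 called members or, with none, the 2 with the smallest p. Of the genes this rule names, 1 is not reported here.

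Footprint and RNA libraries with the same genotype and replicate number were taken as the same culture from the culture codes in their labels. The code of DKO replicate 2 is written differently in the 2 assays, and the column header of its footprints gives it in another spelling, so that the match of this pair is uncertain. The differences between replicates correlated between assays at 0.605 across genes in WT and 0.211 in DKO. WT and DKO cultures of the same number share only the number. The culture therefore entered as a replicate block for translational efficiency alone, as an alternative.

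The procedure was tested on simulated data: counts were drawn for the tested genes from their means, dispersions and library sizes, with 200 genes changed. Each library was drawn independently, with no effect shared by the libraries of a culture and no culture standing apart. For footprints, 72 of 100 genes changed 2-fold and 44 of 100 changed 1.5-fold were recovered, and 14 unchanged genes were called. For RNA the numbers were 81, 54 and 15. For translational efficiency they were 55, 8 and 8, and with the culture block 59, 9 and 18. The unchanged genes called were a larger share of the calls than the threshold of 0.05 allows, most of all with the culture block.

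The alternatives were RLE scaling, TMM within each assay, no filter, a mean count of at least 50 in both assays, DESeq2 1.42.0, limma-voom, the libraries of 1 assay alone, replicate blocks and leaving out each library. Leaving out both libraries of a culture (for WT replicate 2 also with an estimated correlation), and a block with crossed numbers, were added after seeing the data.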

Results

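Ribosome footprints and total RNA were sequenced from mouse neurons labelled as cortical and glutamatergic, at day 8 in vitro, differentiated from CGR8 embryonic stem cells, a feeder-independent mouse line. The neurons were either wildtype (WT) or carried the label of an Eif4g1/Eif4g3 double knockout (DKO). Eif4g1 and Eif4g3 encode scaffold proteins of the complex that brings the ribosome to capped mRNA. Ribosome profiling sequences the mRNA fragments that ribosomes protect, so that footprints measure translation and total RNA measures transcript level. There were 4 groups of 2 libraries, namely footprints of WT, footprints of DKO, total RNA of WT and total RNA of DKO. The footprint libraries held 19753419 and 14450410 estimated counts in WT and 10490535 and 18381021 in DKO. The total RNA libraries held 14762047 and 22352224 in WT and 44786643 and 15862034 in DKO. Values per gene are counts scaled to library size (CPM), given as mean ± SD with n = 2 libraries, and log2 fold changes are DKO over WT with their standard errors (SE). The labels name the libraries as replicates with a culture code each, and the p-values measure the spread between these libraries. The 8 libraries were taken to come from 4 cultures, so that the culture is the replicate of a genotype. The model counted the footprint and RNA libraries of a culture as independent.

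The targeted genes were examined first. Eif4g1 (ENSMUSG00000045983, chromosome 16, 20668313 to 20692884, GRCm38) stood at 299.78 and 263.04 CPM in the WT footprints and at 153.83 and 287.49 CPM in the DKO footprints. In total RNA it stood at 288.29 and 279.88 CPM in WT and at 125.43 and 304.87 CPM in DKO. It was therefore low in both libraries of DKO replicate 1 and within the WT range or above it in those of replicate 2, and the log2 fold change was -0.35 ± 0.52 in footprints (adjusted p = 0.944, edgeR quasi-likelihood test) and -0.41 ± 0.52 in RNA (adjusted p = 0.947). Eif4g3 (ENSMUSG00000028760, chromosome 4, 137993022 to 138208508) stood at 161 ± 10.8 CPM in WT and 168.5 ± 5.67 CPM in DKO footprints, and at 124.2 ± 5.83 CPM in WT and 120.7 ± 25.2 CPM in DKO RNA. Neither gene was called changed. The title of the series speaks of microexons of these genes. The annotation holds a 21-nt coding exon of Eif4g1 at 20674786 to 20674806 on chromosome 16, exon 4 of 33, and a 21-nt coding exon of Eif4g3 at 138095909 to 138095929 on chromosome 4, exon 6 of 35. The count of a whole gene does not show whether such an exon is absent, so these values do not check the genotype labels. The Eif4g1 isoform with the exon took 67.2% and 87.8% of the counts of the isoforms with and without it in WT RNA, and 50.9% and 55.3% in DKO RNA. In footprints the shares were 78.2% and 99.8% in WT and 86.4% and 76.7% in DKO, so the groups overlapped. These isoforms also differ elsewhere, and the shares are estimates from short reads. DKO below stands for the libraries so labelled.

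**Figure D1:**
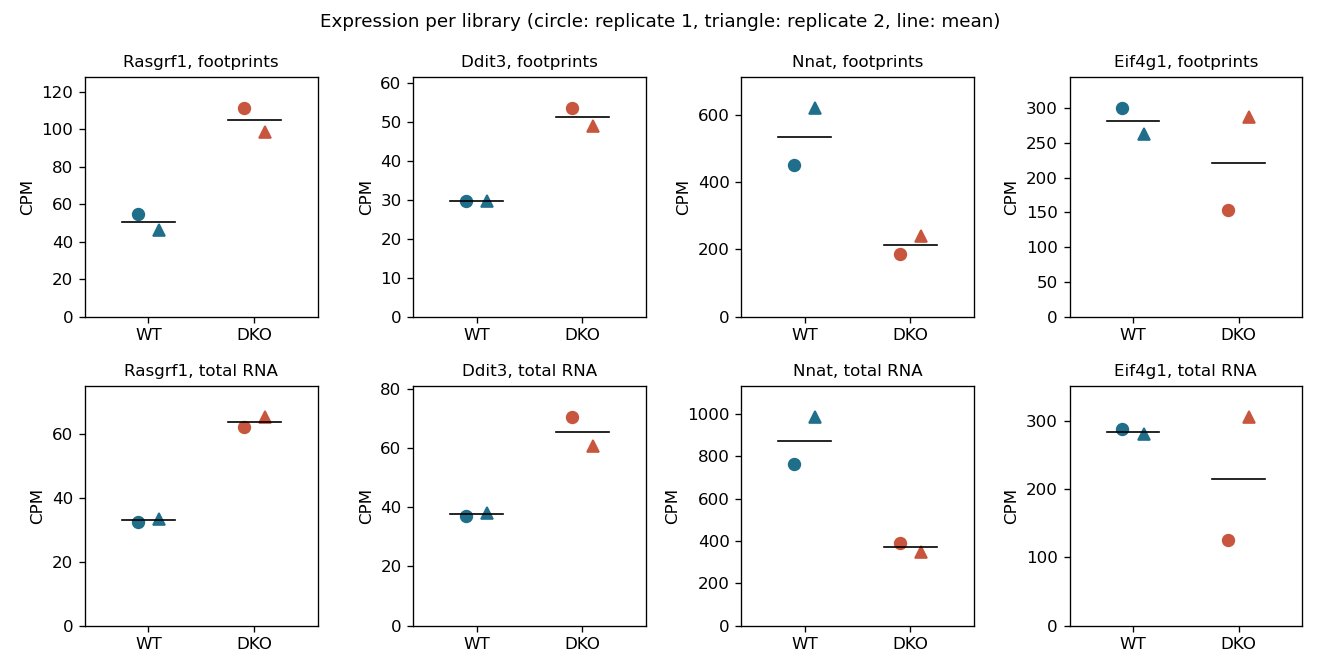
Scaled expression in CPM (vertical axes, starting at 0) of Rasgrf1, Ddit3, Nnat and Eif4g1 in each library, footprints above and total RNA below, with WT in blue and DKO in red. Circles are replicate 1, triangles replicate 2 and lines the mean of 2 libraries. Eif4g1 was low in DKO replicate 1 alone, at 153.83 CPM in footprints and 125.43 CPM in RNA.

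A relative and partners of the targeted proteins were not called in either assay. In footprints the log2 fold change was -0.10 ± 0.11 for Eif4g2, a relative that does not bind the cap-binding protein, 0.02 ± 0.16 for Eif4e, the cap-binding protein, 0.03 ± 0.13 for the helicase Eif4a1, -0.04 ± 0.14 for the poly(A)-binding protein Pabpc1 and 0.03 ± 0.11 for Fmr1, a translational repressor. In RNA the values were -0.11 ± 0.11 for Eif4g2, -0.18 ± 0.16 for Eif4e, -0.01 ± 0.13 for Eif4a1, 0.12 ± 0.14 for Pabpc1 and 0.01 ± 0.11 for Fmr1. Several of these small values changed sign when single libraries were left out.

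The first comparison asked which genes had more or fewer ribosome footprints in DKO neurons. Rasgrf1 (chromosome 9, 89909908 to 90026977), an imprinted gene for a synaptic Ras and Rac exchange factor, rose from 50.4 ± 6.02 CPM in WT to 104.8 ± 8.97 CPM in DKO, a log2 fold change of 1.05 ± 0.11 (adjusted p = 0.00813, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It was the 1 gene called among 12898 tested, and no gene was called lower. Ddit3, the stress-induced transcription factor CHOP, stood at 29.55 ± 0.037 CPM in WT and 51.14 ± 3.19 CPM in DKO but did not pass (log2 fold change 0.79 ± 0.10, adjusted p = 0.0572). The next genes by p among those with higher values were Mageb16 (0.84 ± 0.15, adjusted p = 0.504), the signal peptide peptidase gene H13 (0.53 ± 0.11, adjusted p = 0.837) and Hoxb9, a homeobox gene of the posterior axis (1.42 ± 0.31, adjusted p = 0.837). Those with lower values were led by Nnat, an imprinted gene for a small membrane protein of developing neurons, at 534.8 ± 120 CPM in WT and 213 ± 37.4 CPM in DKO (log2 fold change -1.33 ± 0.19, adjusted p = 0.194). Plagl1, an imprinted zinc-finger gene (-1.23 ± 0.24), Ugt8a, an enzyme of myelin lipid synthesis (-0.60 ± 0.12), Vamp3 (-0.53 ± 0.12) and Itgbl1 (-1.77 ± 0.43) followed with an adjusted p of 0.837 each by edgeR. Itgbl1 had few footprints, at 0.923 ± 0.0305 CPM in WT and 0.2743 ± 0.0536 CPM in DKO. The call of Rasgrf1 was lost in edgeR without footprints of WT replicate 2 (adjusted p = 0.0791), DKO replicate 1 (adjusted p = 0.132) or DKO replicate 2 (adjusted p = 0.0519), at log2 fold changes of 0.94, 0.97 and 1.14. The call of Rasgrf1 was also lost without both libraries of either DKO culture, settings chosen after seeing the data. An unadjusted p under 0.05 was found for 725 genes where 645 would be expected by chance, and DESeq2 called 5 genes.

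Gene lists were tested next. Of the 26 lists tested, 11 passed camera with its preset correlation, and 0 passed with an estimated correlation. Of the 34 tested targets of ATF4 and the integrated stress response, 29 had positive log2 fold changes and 23 lay higher in both DKO libraries than in both WT libraries (median 0.24, camera adjusted p = 1.99e-17, adjusted p = 0.293 with an estimated correlation). Adjusted over the list alone, 8 members passed, against 0 over all genes tested. Ddit3 and Slc3a2, the shared subunit of amino acid transporters (0.43 ± 0.10), had its smallest p-values. Of the 24 activity-induced genes, 21 were positive (median 0.67, camera adjusted p = 8.31e-14, adjusted p = 0.314 with an estimated correlation), among them the immediate early genes Egr1 (0.86 ± 0.20) and Dusp1 (0.82 ± 0.20). Adjusted over the list alone, 3 of them passed. Smaller positive medians were found for postsynaptic scaffolds (0.11, 24 of 34 positive, adjusted p = 0.00183), neurotransmitter receptors (0.10, 29 of 37, adjusted p = 0.0212), presynaptic release genes (0.06, 30 of 35, adjusted p = 0.0434) and ER chaperones (0.04, 11 of 20, adjusted p = 0.0434), all by camera with the preset correlation. With an estimated correlation the adjusted p was 0.869 for the scaffolds, receptors and chaperones and 0.919 for the release genes. The call of the chaperones was lost without footprints of WT replicate 1 (median 0.10), WT replicate 2 (0.05) or DKO replicate 1 (-0.03) and without RNA of either WT replicate (0.03 each), and the median was 0.13 without footprints of DKO replicate 2.

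Markers of dividing and non-neuronal cells lay lower in DKO footprints. All 32 tested proliferation genes had negative log2 fold changes (median -0.41, camera adjusted p = 4.92e-16, adjusted p = 0.647 with an estimated correlation), with Kif23 at -0.78 ± 0.26 and Ccna2 at -0.52 ± 0.18. All 13 oligodendrocyte lineage genes were negative (median -0.29, camera adjusted p = 8.79e-11, adjusted p = 0.314 with an estimated correlation), including the myelin gene Cldn11 (-0.61 ± 0.18), and 4 passed when adjusted over the list alone. The medians were -0.34 for 17 progenitor and radial glia genes (camera adjusted p = 2.73e-07, adjusted p = 0.592 with an estimated correlation), -0.17 for 16 astrocyte genes (camera adjusted p = 0.0434) and -0.60 for 20 fibroblast, mural and endothelial genes (camera adjusted p = 0.00588), both with an adjusted p = 0.869 with an estimated correlation. Libraries of WT replicate 2 stood apart from the rest: the first principal component of the footprints held 56% of the variance and placed it at 34.7 against -9.1, -11.6 and -14 for the others. Its culture code also differs in form from that of WT replicate 1, and whether both WT cultures have the same origin is not given in the sources used here. Without both libraries of that culture, a setting chosen after seeing the data, the median was -0.13 for the proliferation list, -0.26 for the oligodendrocyte list, -0.10 for the progenitor list, -0.01 for the astrocyte list and 0.17 for the fibroblast list, and the synaptic lists were no longer called (medians -0.02 for scaffolds, -0.06 for receptors and -0.05 for release genes), nor were the ER chaperones (0.05), astrocytes and fibroblasts. The ATF4 median was then 0.23 and the activity-induced median 0.41, and both were still called with the preset correlation. With an estimated correlation in that setting the adjusted p was 0.701 for each of them, and 0 lists passed. WT replicate 2 was not the only culture to decide these calls. Without footprints of DKO replicate 2 the scaffolds (0.04), receptors (0.07), release genes (0.05), astrocytes (-0.12) and fibroblasts (-0.19) were not called either. Of the 11 lists, 4 were called whichever single library was left out, namely the ATF4, activity-induced, proliferating and oligodendrocyte lists. The WT cultures differed by 0.64 in the footprint median of the activity-induced list, near the genotype difference of 0.68. In RNA these differences were 0.31 and 0.61. For the ATF4 list they were 0.07 and 0.26 in footprints.

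**Figure D2:**
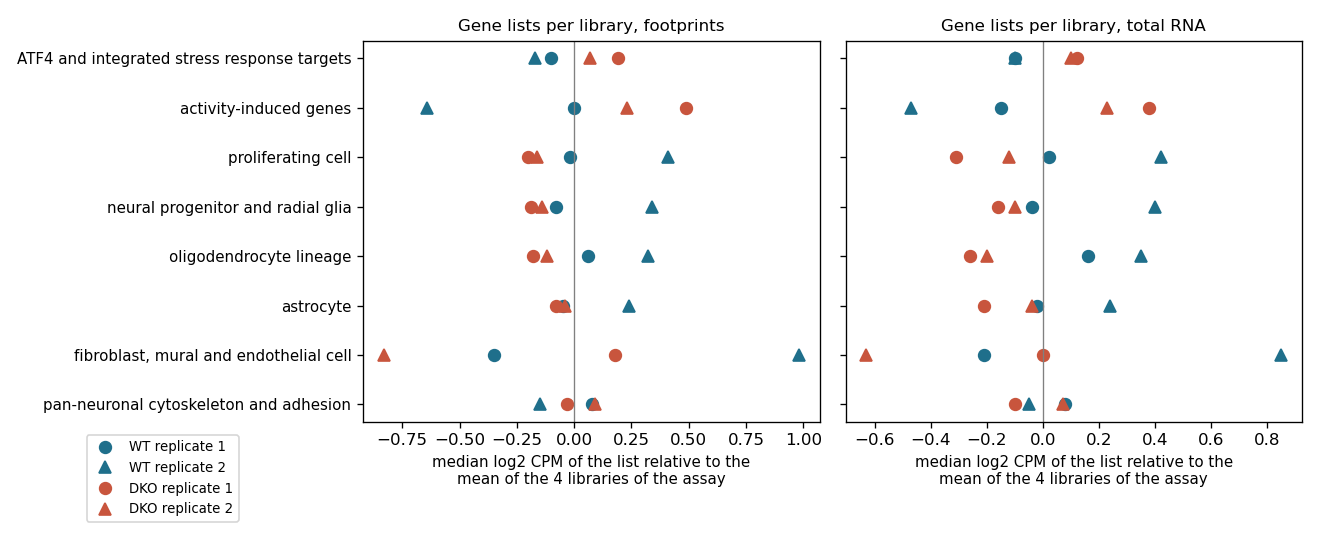
Median log2 CPM of the genes of 8 lists in each library, relative to the mean of the 4 libraries of the assay (horizontal axes), for footprints on the left and total RNA on the right. WT is blue, DKO red, circles replicate 1 and triangles replicate 2. WT replicate 2 lies highest in the proliferating, progenitor and glial lists, at 0.41 for proliferating cells in footprints, and both DKO libraries lie above both WT libraries in the ATF4 list.

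The second comparison asked the same of transcript level. Rasgrf1 RNA rose from 33.01 ± 0.673 CPM in WT to 63.72 ± 2.03 CPM in DKO (log2 fold change 0.95 ± 0.11, adjusted p = 0.0242, edgeR), and Ddit3 RNA rose from 37.66 ± 0.665 to 65.69 ± 6.78 CPM (0.80 ± 0.10, adjusted p = 0.0291, edgeR). These were the 2 genes called, and 0 were called lower. Not passing, the genes next in order were Trim66 (1.10 ± 0.21), Egr1 (1.04 ± 0.20) and Cpeb1, which binds the cytoplasmic polyadenylation element (0.61 ± 0.12), on the higher side. On the lower side they were Nnat (-1.24 ± 0.19, adjusted p = 0.219), Cand2 (-1.12 ± 0.18), Plagl1 (-1.41 ± 0.24), Snx22 (12.85 ± 0.18 CPM in WT and 6.417 ± 0.182 CPM in DKO) and Ugt8a (-0.59 ± 0.12). The RNA calls of both Rasgrf1 and Ddit3 were lost without RNA of WT replicate 1, WT replicate 2 or DKO replicate 1, and without footprints of either DKO replicate, which enter the shared estimate of the spread. With the 4 RNA libraries alone Ddit3 was not called (adjusted p = 0.106, edgeR). The adjusted p over these 5 settings was 0.1 to 0.213 for Rasgrf1 and 0.129 to 0.425 for Ddit3 (edgeR). Both RNA calls were also lost without both libraries of WT replicate 2, DKO replicate 1 or DKO replicate 2, settings chosen after seeing the data. Over all libraries and cultures left out, the log2 fold change in RNA was 0.92 to 0.99 for Rasgrf1 and 0.69 to 0.94 for Ddit3.

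In RNA, 11 of the 26 lists passed camera with the preset correlation and 0 with an estimated one. The ATF4 targets had 29 of 34 positive values (median 0.20, camera adjusted p = 2.89e-15, adjusted p = 0.323 with an estimated correlation), and 6 passed when adjusted over the list alone, against 1 over all genes. The activity-induced genes had 20 of 24 positive values (median 0.69, camera adjusted p = 2.16e-14, adjusted p = 0.325 with an estimated correlation), with Fosb at 1.40 ± 0.32, and 8 passed over the list alone. The median was -0.41 for the oligodendrocyte list (camera adjusted p = 2.64e-13), with Cldn11 at -0.85 ± 0.18, and -0.47 for the proliferating list (camera adjusted p = 2.42e-19), with Mcm6 at -0.55 ± 0.15 and Top2a at -0.53 ± 0.15. It was -0.36 for progenitors (camera adjusted p = 3.7e-08), -0.32 for astrocytes (4.53e-06), -0.65 for fibroblast, mural and endothelial genes (0.00239), -0.05 for imprinted genes (0.0159) and -0.16 for cytosolic heat shock proteins (0.0455). Ribosomal protein and elongation factor genes lay slightly higher, 82 of 89 being positive (median 0.11, camera adjusted p = 1.57e-06), and the postsynaptic scaffolds had a median of 0.10 (camera adjusted p = 0.000206). With an estimated correlation the adjusted p was 0.323 for the oligodendrocyte list, 0.423 for the proliferating, progenitor, astrocyte and imprinted lists, 0.653 for the scaffolds, 0.701 for the heat shock proteins and 0.752 for the fibroblast and ribosomal protein lists. Of the 11 lists, 7 were called in the same direction whichever single library was left out. The call of the heat shock proteins was lost without 7 of the 8 single libraries (medians -0.22 to -0.03 over all 8) and with RLE scaling (adjusted p = 0.0516, camera), that of the imprinted genes without 3 of the 8 (-0.06 to 0.00), and that of the fibroblast list without RNA of WT replicate 2 (-0.01) or DKO replicate 2 (-0.43). Without RNA of DKO replicate 1 the ribosomal protein median turned to -0.04, and without both libraries of that culture to -0.055. In both settings the list was called lower with the preset correlation, so its direction rests on that culture. WT replicate 2 stood apart in RNA as well, at 29.3 on a first component with 56.4% of the variance. Without both of its libraries the median was -0.37 for the oligodendrocyte list, -0.20 for the proliferating list, -0.11 for progenitors, -0.12 for astrocytes, -0.02 for imprinted genes, 0.20 for the ATF4 targets, 0.41 for activity-induced genes and 0.08 for the scaffolds, all called with the preset correlation. The fibroblast (-0.01), ribosomal protein (0.06) and heat shock (-0.12) lists were no longer called, and 0 lists passed with an estimated correlation.

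The third comparison asked whether translational efficiency, the footprints relative to RNA, differed between genotypes. TMM scaling sets the typical gene near no change (median log2 change 0.011). A change of translation shared by all genes would therefore not be seen, and the comparison covers only genes and lists relative to the rest. No gene passed the interaction test (edgeR quasi-likelihood, smallest adjusted p = 1), and 110 genes had an unadjusted p under 0.05 where 645 would be expected by chance. So large a deficit means that this test ran conservative, and the deficit is no evidence that efficiency was unchanged. The model took the footprint and RNA libraries of a culture as independent, although replicate differences correlated between assays at 0.605 in WT and 0.211 in DKO. limma-voom called 0 genes and DESeq2 called 1, Il17f (adjusted p = 0.0428). With the culture as a replicate block the count was also 0 (smallest adjusted p = 0.246, 300 genes at an unadjusted p under 0.05). The genes with the smallest p on the higher side were Il17f (log2 change 1.30 ± 0.25), Plau (1.41 ± 0.34), Fam221b (1.84 ± 0.45), Armt1 (0.60 ± 0.15) and Cand2 (0.92 ± 0.25). On the lower side they were Gipc2 (-1.69 ± 0.42), Tmem254c (-1.46 ± 0.40), Knop1 (-0.45 ± 0.13), Itgbl1 (-1.72 ± 0.48) and Zfp963 (-0.51 ± 0.16). Il17f had 2.136 ± 0.246 CPM in WT footprints against 672 ± 26.4 CPM in WT RNA, so its ratio rests on few footprints. The same holds for Plau (1.189 CPM in WT footprints), Fam221b (1.06), Itgbl1 (0.923), Gipc2 (2.008) and Tmem254c (3.304). Armt1 (11.6), Zfp963 (18.15), Cand2 (26.09) and Knop1 (46.97) had more. In simulated counts the interaction test recovered 55 of 100 genes with a 2-fold change and 8 of 100 with a 1.5-fold change. Changes of 1.5-fold in single genes were thus rarely recovered there, and sizes between these were not simulated. The simulated libraries shared no effect of a culture, so these shares may not hold for the real libraries.

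Of the 26 lists, 7 passed camera in translational efficiency with the preset correlation and 0 with an estimated one, where the adjusted p was 0.978 for each. Of the 89 ribosomal protein and elongation factor genes, 81 had lower efficiency values in DKO (median -0.11, camera adjusted p = 5.04e-08), with Rps13 at -0.30 ± 0.18 and Rpl22 at -0.26 ± 0.17. The median was positive for glycolysis and lactate transport (0.12, 20 of 23 positive, adjusted p = 0.00532), cytosolic heat shock proteins (0.13, 13 of 14), ER chaperones (0.10, 16 of 20), pan-neuronal genes (0.09, 19 of 23), FMRP-bound transcripts (0.08, 44 of 63) and astrocyte genes (0.14, 13 of 16), the last 5 with a camera adjusted p of 0.0391 each. With the culture as a replicate block 10 lists passed. Each of the 7 calls was lost without some single library, and without RNA of DKO replicate 1 all 7 were. Without both libraries of WT replicate 2 none passed. Without both libraries of DKO replicate 1 the ribosomal protein median turned to 0.08, and the list was called higher with the preset correlation.

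Across the 12898 tested genes, the log2 fold changes of footprints and RNA had a Pearson correlation of 0.618 and a Spearman correlation of 0.549; genes are not independent replicates, and no p-value is attached. Of 228 genes with an unadjusted p under 0.05 in both assays, 224 had the same sign, against 20.2 if the assays were independent. The assays share their cultures, so a culture that stands apart moves both. The correlation was 0.628 and 0.692 when each DKO culture was set against WT replicate 2 alone, and 0.278 and 0.245 against WT replicate 1 alone. Without both libraries of WT replicate 2 it was 0.251.

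**Figure D3:**
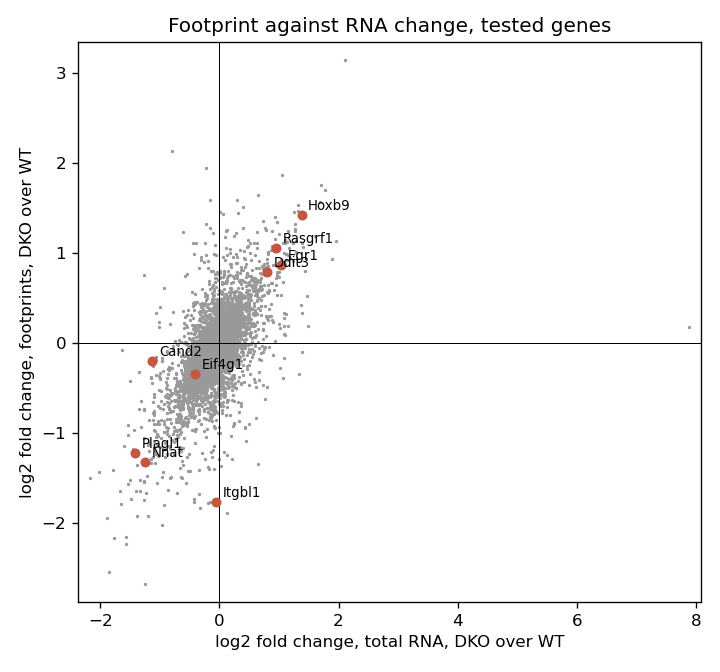
Log2 fold change of DKO over WT in total RNA (horizontal axis) against that in footprints (vertical axis) for the 12898 tested genes in grey, with 9 genes named in red. The Pearson correlation across genes was 0.618, and Rasgrf1 lies at 0.95 in RNA and 1.05 in footprints.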

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

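With 2 libraries per group no library could be tested as an outlier. The genes below were picked out because both DKO libraries lay on one side of both WT libraries in footprints and on the other side in RNA. Of the 149 named genes 11 did so, as did 1.8% of all tested genes, where independent assays would give 5.56% by chance. Plau, Il17f, Fam221b, Armt1, Knop1, Tmem254c and Zfp963 had been named for their small p in translational efficiency, which favours this pattern. The share among named genes can therefore not be set against that of all genes. The difference between the assays was higher for Plau (log2 change in translational efficiency 1.41), Il17f (1.30), Fam221b (1.84), Armt1 (0.60), Ep400 (0.24) and Cux2 (0.28), and lower for Homer2 (-0.44), Knop1 (-0.45), Uqcrh (-0.24), Tmem254c (-1.46) and Zfp963 (-0.51). None of the 11 passed the interaction test of edgeR (adjusted p of 1 each).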

How the results depend on the processing

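The replicate block by number gave 11 footprint genes, 10 RNA genes and 0 genes in translational efficiency, against 1, 2 and 0 without it. Deviations of same-numbered WT and DKO libraries from their group means correlated across genes at -0.132 in footprints and -0.128 in RNA. Crossing them, a test chosen after seeing the data, gave 9 footprint and 11 RNA genes. The replicate block by culture kept translational efficiency at 0 genes and gave 10 lists. Without a filter 3 footprint and 6 RNA genes were called, with a mean count of at least 50 there were 2 footprint genes, DESeq2 called 5, 13 and 1, and the 4 RNA libraries alone gave 1 gene, without Ddit3. The cause was not tested. RLE scaling, TMM within each assay and limma-voom changed no gene count by over 1.5 times. With an estimated correlation, and with fry, 0 lists passed in each of the 3 comparisons, against 11, 11 and 7. Nor did any with an estimated correlation without both libraries of WT replicate 2, a setting chosen after seeing the data (0 in each). The correlation of footprint and RNA changes was 0.144 without a filter, where genes with few counts enter.

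Leaving out a library, or (chosen after seeing the data) both libraries of a culture, gave 0 to 520 footprint genes, 0 to 473 RNA genes, 0 to 1 gene in translational efficiency, 7 to 18 footprint lists, 9 to 16 RNA lists, 0 to 17 lists in translational efficiency, and a correlation of 0.189 to 0.67. The highest gene counts, 520 and 473, came without both libraries of WT replicate 1, which leaves WT replicate 2 as the sole WT culture. A lone library is then assumed to vary like the other groups. The correlation was 0.189 without footprints and 0.202 without RNA of WT replicate 2.

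The same settings turned the sign of some list medians or of their tests. The footprint medians ran from -0.049 to 0.223 for presynaptic release, -0.057 to 0.267 for receptors, -0.016 to 0.241 for scaffolds, -0.026 to 0.132 for ER chaperones, -0.267 to -0.008 for astrocytes and -1.239 to 0.178 for fibroblasts. The RNA median of ribosomal proteins ran from -0.055 to 0.282. In translational efficiency the medians ran from -0.039 to 0.212 for FMRP-bound transcripts, -0.295 to 0.08 for ribosomal proteins, 0.013 to 0.194 for ER chaperones, -0.048 to 0.207 for pan-neuronal genes and -0.048 to 0.305 for astrocytes. Log2 fold changes in footprints ran from -0.867 to 0.035 for Eif4g1, -0.003 to 0.154 for Eif4g3, -0.274 to 0.267 for Eif4e, -0.059 to 0.132 for Eif4a1, -0.089 to 0.016 for Pabpc1, -0.137 to 0.237 for Fmr1 and -3.055 to 0.203 for Tagln. In RNA they ran from -1.178 to 0.114 for Eif4g1, -0.271 to 0.169 for Eif4g3, -0.091 to 0.104 for Eif4a1 and -0.115 to 0.348 for Pabpc1. In translational efficiency they ran from -0.467 to 0.795 for Eif4g1, -0.11 to 0.307 for Eif4g3, -0.076 to 0.068 for Eif4g2, -0.162 to 0.514 for Eif4e, -0.094 to 0.193 for Eif4a1, -0.4 to 0.08 for Pabpc1, -0.158 to 0.225 for Fmr1 and -0.028 to 0.362 for Nrcam. Eif4g2 was also at -0.003 with RLE scaling, without a filter and with DESeq2. None of these genes was called in the main model. For single named genes, 818 values under the other settings kept their direction and side of the threshold, 27 newly passed it, 1 no longer did and 3 changed sign. With libraries or cultures left out the counts were 1069, 35, 21 and 63.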

Other observations

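The tests of WT replicate 2 as the cause for the proliferating, oligodendrocyte and fibroblast lists, including the comparison with other cultures left out, the comparison of the microexon isoform with the WT cultures, and the percentiles without Igf2, were chosen after those results were seen. Several lists were not called in any comparison. In footprints and RNA the medians were 0.03 and 0.03 for voltage-gated ion channels, -0.03 and -0.01 for nuclear genes of oxidative phosphorylation, -0.04 and -0.09 for cholesterol synthesis, 0.04 and 0.00 for autism-associated genes, 0.05 and 0.05 for translation initiation, -0.05 and -0.06 for glutamatergic cortical neurons, -0.03 and -0.16 for GABAergic neurons, -0.14 and -0.16 for hindbrain and spinal identity, and -0.58 and -0.70 for epithelium and endoderm. In footprints the mean and the test of the ion channels were negative despite the positive median, those of the glutamatergic list were positive despite the negative median, and the mean of the GABAergic list was positive in both assays. Without both libraries of WT replicate 2, a setting chosen after seeing the data, further lists passed with the preset correlation, and 0 lists passed with an estimated one. Cholesterol synthesis (-0.154 in footprints and -0.239 in RNA) and oxidative phosphorylation (-0.067 and -0.071) were then lower in both assays, and epithelium and endoderm turned to higher (0.45 and 0.465). The ion channels (-0.057) and imprinted genes (0.001, with a negative test) were called lower in footprints, and receptors (-0.077), glycolysis (-0.08) and pan-neuronal genes (-0.094) in RNA. Markers of pluripotent cells, and of microglia and blood, had 4 and 2 tested members. Cisd3 took 4289 to 9545 CPM of the RNA libraries and 14.68 to 18.38 CPM of the footprint libraries.

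Eif4g1 was low in DKO replicate 1 alone, at 0.54 times the geometric mean of the other 3 cultures in footprints and 0.43 times in RNA. Of 12898 genes, 154 lay as low or lower in footprints and 14 in RNA. The median log2 ratio of DKO replicate 1 to replicate 2 was -0.005 over all genes in RNA. TMM scaling sets this median near 0, so it cannot decide whether depth or scaling had a part. A scaling factor shared by all genes of a library would not change the rank of Eif4g1 among them. That low rank argues against such a factor as the cause. A deletion reaching the neighbours is argued against by the 12 tested genes within 100 kb, whose median log2 ratio was 0.10 in RNA. Loss of reads at a missing microexon alone is argued against by the size of the exon. It has 21 nt in a transcript of 33 exons, while the count of the whole gene was 0.43 times that of the other cultures in RNA. DKO replicate 2, with the same label, stood at 304.87 CPM in RNA and 287.49 CPM in footprints. The comparison of isoforms cannot decide this question. The isoform without that exon was lower in DKO replicate 1 than in DKO replicate 2 by a log2 ratio of -1.15, past the bound set beforehand against this explanation, but that bound was wrong, since in RNA the isoform stood at 58.4 CPM in DKO replicate 1, above the 32.5 CPM of WT replicate 2, and at 89.9 and 130 CPM in the others.

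Imprinted genes were among the largest changes in both directions, with Nnat, Plagl1 and Mest (-1.36 in footprints) lower and Dlk1 (0.85) higher. The imprinted genes below are the 16 tested members of the fixed list, which does not hold Rasgrf1. The mean absolute log2 fold change of the 16 tested imprinted genes was 0.52 in footprints and 0.45 in RNA, at percentile 100 of 10000 random lists matched on expression in both, and it stayed at percentile 100 in RNA without WT replicate 2. This argues against a random draw of genes of like expression. The random lists do not measure the spread between cultures, so they cannot exclude a chance difference between them. Imprinted genes also differed between cultures of 1 genotype, at percentile 99.9 in RNA for both WT and DKO, so that these genes varied between cultures apart from the genotype. Without Igf2 the percentile was 95.7 in RNA and 99.5 in footprints for WT, and 83 and 91.2 for DKO, so that the part in DKO rests on Igf2. No imprint or allele was measured, and with 2 cultures per genotype an effect of the genotype on these genes stays open.

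Proliferating, progenitor, glial and fibroblast lists were called lower in DKO with the preset correlation, and none of them was called with an estimated one. For the fibroblast list WT replicate 2 alone as the cause stays open. The call of that list in both assays ended without that culture (footprint median 0.171) but also without DKO replicate 2 (-0.279). WT replicate 1 lay between the DKO cultures and not above both. In footprints WT replicate 1 stood at -0.35, DKO replicate 1 at 0.18 and DKO replicate 2 at -0.83. In RNA they stood at -0.21, 0.00 and -0.63. Of the 20 genes, 0 lay lower in both DKO than in both WT libraries in footprints, and 5 in RNA. For the oligodendrocyte list WT replicate 2 is argued against as the whole cause in RNA, where WT replicate 1 itself lay above the nearer DKO culture by 0.36. The DKO cultures were 0.06 apart there, and the difference of WT replicate 1 minus 2 was -0.19. In footprints the gap was 0.18 and the DKO cultures were 0.06 apart, but the WT difference was -0.26, so that this cause stays open there. For the proliferating list WT replicate 2 alone as the cause stays open, because the same gap was 0.14 in both assays and the DKO cultures were 0.04 apart in footprints and 0.19 in RNA. Both lists were still called lower without that culture with the preset correlation (oligodendrocyte footprint median -0.265, proliferating -0.133), and neither was called with an estimated correlation, with or without that culture. A clonal difference and an effect of the genotype cannot be told apart: the difference between the WT cultures in RNA was 0.40 times the genotype difference in the oligodendrocyte list, the smallest ratio of the 4 lists, and there are 2 cultures per genotype. In footprints the WT difference in the oligodendrocyte list was -0.26 and the genotype difference -0.34.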
